A study of Rattus norvegicus with 2 samples.

How the data were processed

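Esophageal tissue of male Sprague-Dawley rats, a common outbred laboratory strain, was profiled on Affymetrix Rat Genome 230 2.0 arrays, the array type per the series design text. The rats had received the HDAC inhibitor OSU-HDAC42 or vehicle. HDACs are histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. Per the labels' protocols, 7 doses of 50 mg/kg body weight were given by gavage up to a total of 350 mg/kg, and tissue was taken on day 15, 24 hours after the last dose. The labels give 1 array for each of the 2 groups and do not say whether an array held RNA of 1 rat or of several. They name Trizol for the RNA extraction, whereas the series design text names a column kit. Biotin-labelled cRNA was hybridised, per the labels' protocols.

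The deposited values are probe set intensities on a linear scale, with 1 value per probe set and array. That unit was read from the values, which ran from 4.54 to 14438 on the OSU-HDAC42 array and from 4.48 to 14947 on the vehicle array outside the control probe sets. GCOS and RMA are named per the submitters' processing notes, with no role, order or version given in the sources used here. How the authors scaled the arrays to each other is also not given there. Of the intensities over 50, 9.51% on the OSU-HDAC42 array and 9.59% on the vehicle array were multiples of 0.5 plus the same remainder of 0.296, in a window 0.0005 wide, where 0.1% would be by chance. Such a spacing would arise if probe intensities of both arrays had been averaged rank by rank, as quantile normalization does, and any difference in total signal between the arrays would then have been removed. No source used here states that step. The median intensity was 48.4 on the OSU-HDAC42 array and 49.1 on the vehicle array. Across all probe sets the log2 values of the arrays had a Pearson correlation of 0.987, which describes probe sets and not independent replicates, and 963 non-control probe sets held exactly equal deposited values on both arrays, before any value was raised.

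The design fixed before the data were examined took the values for log2 values and set a fallback for linear ones. The fallback was used: intensities under 16 were raised to 16 and log2 was taken. This touched 28.4% of probe sets on the OSU-HDAC42 array and 29.2% on the vehicle array. A gene with 1 array under 16 has only a bound on its difference, given as "at least". No further normalization was applied.

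Of 31099 probe sets, 57 are Affymetrix controls and were kept out of gene results, including those with a gene symbol. For the other 31042 the platform annotation gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780. Probe sets with several symbols or none were not used for genes. Of the resulting 14217 genes, 14167 had their symbol in the RefSeq gene table of the GRCr8 rat assembly. That assembly was not tied to the array's probes, so positions in the genome are not given. Each gene was represented by the probe set with the highest mean of both arrays.

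All differences are log2 intensity on the OSU-HDAC42 array minus log2 intensity on the vehicle array. A gene was counted as at least 2-fold higher or lower when its difference reached that size and its higher array reached an expression floor. The floor was the median over non-control probe sets of the mean of both arrays, an intensity of 49.1. With no replicates, the differences carry no p-value and no standard error. The number of arrays limits the precision, and neither the spread between rats nor that between hybridisations can be estimated. The only measure of error was the spread between probe sets of the same gene, which covers probe noise alone.

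A total of 47 gene lists with 1138 memberships was fixed before the data were examined, and 978 memberships matched a measured symbol, 32 of them through an older symbol. For 3 further symbols the older name belonged to another gene, and these were set aside before list values were computed. For each list, the median difference over measured members was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its percentile was under 2.5 or over 97.5. These percentiles describe the arrays and are not p-values, and 2.35 of 47 lists would stand apart by chance on average if lists were independent and their members varied independently, which they need not. Where most members were under 16 on both arrays, raising the values fixed the median at 0, and the comparison says nothing about such a list.

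Named genes followed a rule fixed before the data were examined. It took, in each direction, the 15 genes with the largest difference among those counted as 2-fold, provided that their other probe sets above the floor went the same way. Symbols beginning with LOC or RGD, or marked as predicted or mapped, were not named. It also took up to 4 members of each list, above the floor, with the largest differences, and the whole list of HDAC genes. Genes named outside this rule are stated to have been chosen after their values were seen.

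The counting and the list comparison were tested on simulated data built on the real 14217 genes with probe noise alone, of 1 size at all intensities. Changed genes and list members were drawn only from genes at least 1.5 log2 units above the expression floor. The shares below therefore do not describe dimmer genes, and real differences spread more at low than at high intensities. Among 50 genes set at each size, the step counted 4% of those changed 1.5-fold, 50% at 2-fold, 100% at 3-fold and 100% at 4-fold, and it counted 2 of 9206 unchanged genes. A simulated list shifted by 0.6 reached percentile 100, and an unchanged one percentile 52.1. Differences between rats were not part of this simulation.

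The alternatives fixed beforehand were centring each array on its median, quantile normalization, removal of a lowess trend (span 0.3), the mean or median over probe sets of a gene, omission of probe sets shared between transcripts, other expression floors, thresholds of 1.5-fold and 3-fold, list means, and unmatched random lists. Raising no values, raising values under 32 to 32, and omitting members shared with the skeletal muscle list were added after the data were seen. Tests in the closing section were also chosen after the values were seen. Bootstrap intervals there are 95% intervals from 10000 draws over genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 drew the plots.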

Results

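Genome-wide expression was compared between esophageal tissue of rats given the HDAC inhibitor OSU-HDAC42 and esophageal tissue of rats given vehicle. The series title gives the question as the effect of this inhibitor on gene expression in esophageal tissue. Each group had 1 array with 31042 non-control probe sets, and there were no replicates, so no value below has an error between rats. In total, 9560 genes reached the expression floor on at least 1 array.

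In the OSU-HDAC42 sample, genes of the skeletal muscle fibre were much lower than in the vehicle sample, and 25 of the 41 skeletal muscle genes above the floor were at least 2-fold lower. Genes of cell division, of smooth muscle and of the extracellular matrix were higher. Genes of the circadian clock differed in both directions, with Bmal1 5.76-fold higher and Dbp 3.89-fold lower. Lists of genes often reported as higher or lower after HDAC inhibition did not stand apart from random lists. Of the genes above the floor, 180 (1.88%) were at least 2-fold higher and 303 (3.17%) at least 2-fold lower in the OSU-HDAC42 sample, and for 3 of the lower genes the difference is only a bound. The log2 differences of all genes above the floor had a median of -0.027 and an SD of 0.48. Probe sets of the same gene differed from each other with an SD of 0.41 over 3643 pairs in 2126 genes. Of 62 other probe sets above the floor that measured genes counted as 2-fold, 59 (95.2%) went the same way and 25 (40.3%) were 2-fold themselves.

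**Figure D1:**
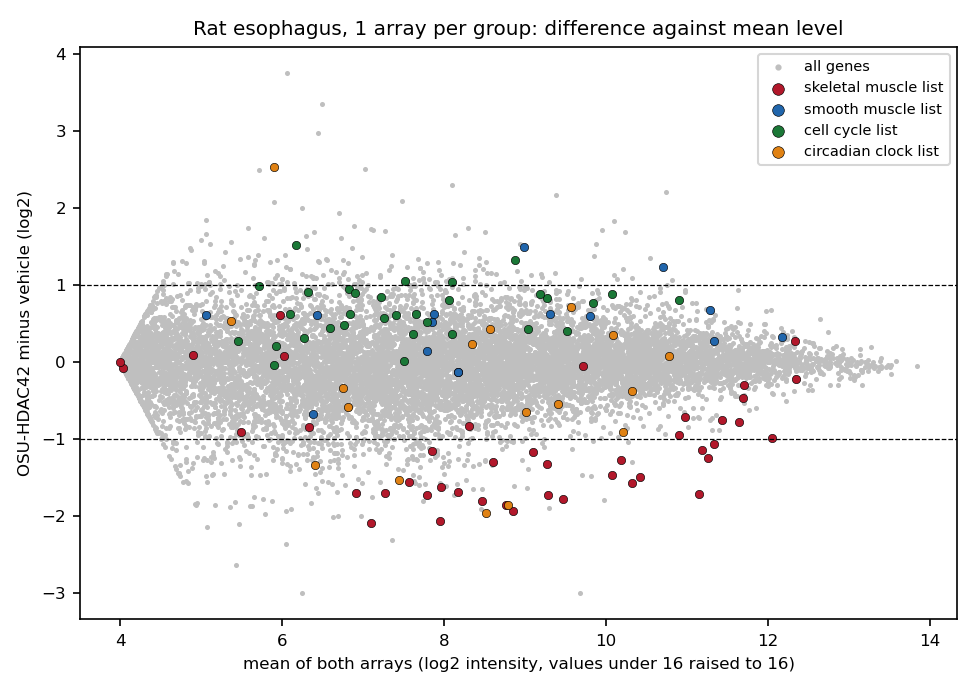
Log2 difference (OSU-HDAC42 minus vehicle, vertical axis) against the mean log2 intensity of both arrays (horizontal axis), 1 grey point per gene, with skeletal muscle, smooth muscle, cell cycle and circadian clock genes in colour and dashed lines at 2-fold. Skeletal muscle genes lie mostly below 0 with a median of -1.16, and cell cycle genes mostly above 0 with a median of 0.63.

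The gene with the largest difference among those named was Rem2, a small GTPase of the RGK family that inhibits voltage-gated calcium channels, with an intensity of 288 on the OSU-HDAC42 array and 28.2 on the vehicle array (10.2-fold). Nyap1 was 7.84-fold higher. Bmal1, the core activator of the circadian clock, had intensities of 143 and 24.7. Wasf1, an activator of actin branching, was 5.69-fold higher, Ypel4 5.64-fold and Pde4c, a cAMP phosphodiesterase, 4.93-fold. Sprr1b, a precursor of the cornified envelope of squamous epithelium, stood at 3688 against 799 (4.61-fold). Serpina12, the adipokine vaspin, stood at 1409 against 315 (4.48-fold). Armcx2 was 4.26-fold higher, Tspan18 4.23-fold, Chct1 3.83-fold and the histone gene H4f3 3.59-fold, and Prr36 stood at 151 against 37.9. Blvrb, a biliverdin reductase, stood at 2066 against 582 (3.55-fold), and Dact3, an antagonist of Wnt signalling, was 3.41-fold higher. The gene Harbi1 had a larger difference but was not ranked, because its probe sets went in opposite directions (3.75 and -1.84).

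Among the lower genes, Pcp4, a calmodulin-binding protein, stood at 26.8 against 214 (7.98-fold). Abca1, the transporter that passes cholesterol to apolipoprotein A-I, stood at 290 against 2312 on its brightest probe set (7.98-fold), while its other probe set above the floor differed by only -0.15. The next genes are known from striated muscle and were grouped after their values were seen, and only Actn3, Ampd1 and Ttn stand on the skeletal muscle list. Ky was 6.18-fold lower, Smtnl1 4.97-fold, Actn3 4.25-fold, Ampd1 4.19-fold, Nrap 4.01-fold, Lmod3 3.98-fold, Dhrs7c 3.92-fold and Ttn 3.83-fold. Mypn was under 16 on the OSU-HDAC42 array and 70.6 on the vehicle array, at least 4.41-fold lower. Aqp4, a water channel also found in the membrane of fast muscle fibres, was 5.12-fold lower. Dbp, a transcription factor driven by the clock, was 3.89-fold lower, RT1-Bb, a class II histocompatibility chain, 4.27-fold and Cdyl2 3.99-fold.

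The rat esophagus has an outer coat of skeletal muscle, and all 44 genes of the skeletal muscle list were measured. Of the 41 above the floor, 38 were lower in the OSU-HDAC42 sample. The list median was -1.16 (2.24-fold lower), below all 10000 random lists. Actn3, the alpha-actinin of fast fibres, differed by -2.09, Ampd1, the AMP deaminase of muscle, by -2.07, the giant sarcomere protein Ttn by -1.94, and the myosin-binding protein Mybpc1 by -1.85. Of genes usual in slow fibres, which were chosen after their values were seen, the troponins Tnnt1 and Tnni1 differed by 0.62 and 0.078 and the light chain Myl3 by -1.27, and Myh7 and Tnnc1 were below the floor. The labels do not say which layers of the esophagus were taken. Neuromuscular junction and denervation genes did not stand apart as a list (17 measured, median -0.056, percentile 22.6), although the 8 members above the floor had a median of -0.56 and did (percentile 2.33). Their muscle regulators Myog, Myod1 and Myf6 each differed by -1.07, and the acetylcholine receptor subunit Chrnb1 by -1.19.

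Smooth muscle genes were higher. Of 13 genes above the floor, 11 were higher and 2 lower, with a list median of 0.60 over 14 measured genes, above all random lists. Synpo2, an actin-binding protein of the Z-disc and dense bodies, was 2.83-fold higher, the contractile-cell marker Tagln 2.36-fold and enteric actin Actg2 1.60-fold, while Hspb7 differed by -0.67. Fibroblast and extracellular matrix genes were also higher (37 measured, 26 of 34 above the floor higher, median 0.24, percentile 100). Among them were the collagen cross-linking enzyme Lox at 1.30, Col12a1 and Thy1 at 1.09 each and the growth factor receptor Pdgfra at 0.94. Endothelial genes were lower in 10 of 14 cases (median -0.51, percentile 0.10), with Vwf at -0.95, Ramp2 at -0.90, Mmrn2 at -0.83 and Egfl7 at -0.79. With the endothelial list limited to its 4 members above the 75th percentile of intensities, its median was 0.041.

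Keratinocyte lists did not stand apart from random lists. Many of their genes were very bright, and Krt13 had the highest intensity of both arrays outside the controls. Differences of such genes were small throughout (SD 0.16 at mean log2 intensities over 12), which limits what could be seen. The basal keratinocyte list had a median of -0.079 (18 measured, percentile 18.5), with the hemidesmosome integrin Itgb4 at -1.28, Itga3 at -0.62, the hemidesmosome collagen Col17a1 at -0.46 and Pdpn at 0.58. The suprabasal and cornified squamous list had a median of -0.068 (28 measured, percentile 4.08), and 18 of 27 genes above the floor were lower. Against this, 3 of its genes were at least 2-fold higher, namely Sprr1b at 2.21, the keratin Krt6c at 1.68 and the suprabasal keratin Krt10 at 1.04, and the envelope protein Evpl differed by -0.69.

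**Figure D2:**
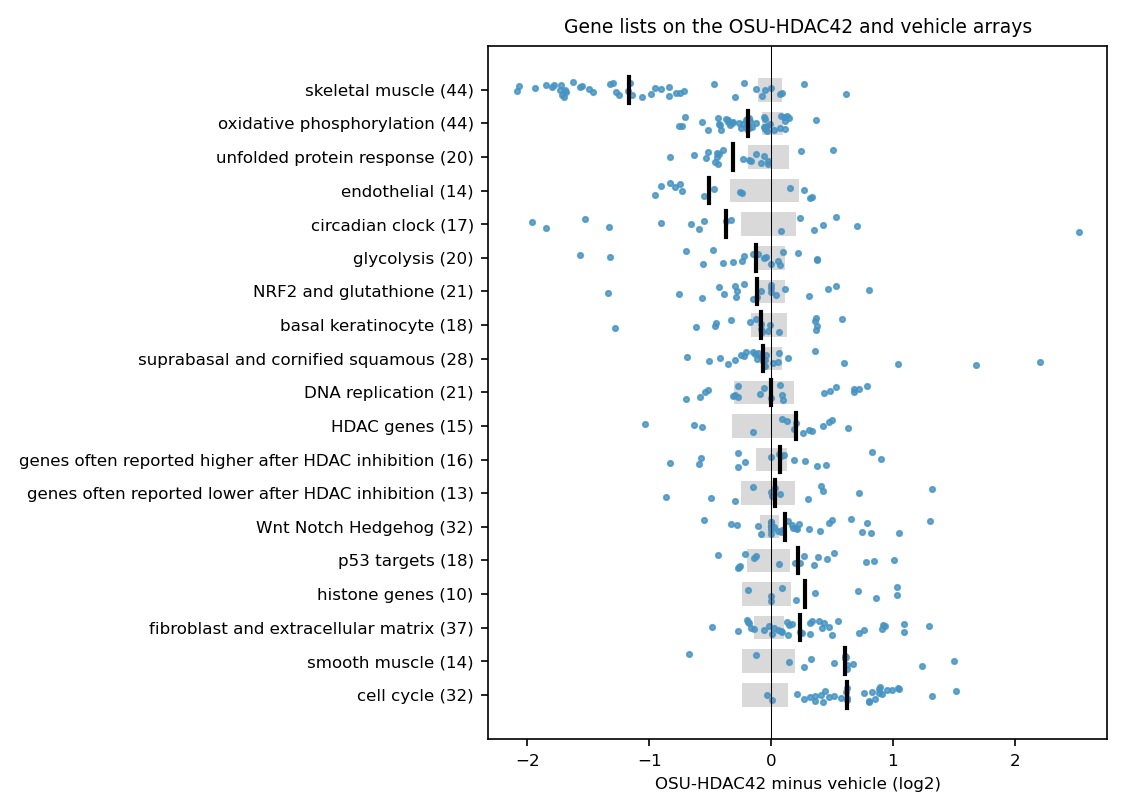
Log2 difference (OSU-HDAC42 minus vehicle, horizontal axis) of each measured member of 19 gene lists (points), the list median (black line) and the central 95% of medians of matched random lists (grey bar), with the number of measured members in brackets. Medians run from -1.16 for skeletal muscle to 0.63 for the cell cycle.

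Cell cycle genes were higher almost throughout. Of 31 above the floor, 30 were higher and 1 lower, and the list median of 0.63 (1.54-fold) over 32 measured genes lay above all random lists. Ccne1, the cyclin of entry into S phase, differed by 1.52, the mitotic regulator Birc5 by 1.32, the kinase Melk by 1.05 and Cdca3 by 1.04. DNA replication genes did not share this shift (21 measured, median 0.00, percentile 69.2). Of the replication genes above the floor, 9 were higher and 9 lower, with the flap endonuclease Fen1 at 0.72, Cdt1 and Prim1 at 0.68 each and the helicase subunit Mcm3 at -0.69. The histone list was higher by its median (10 of 26 listed genes measured, median 0.28, percentile 99.7). Of its 7 members above the floor, 6 were higher and 1 lower, and 2 of the 10 were under 16 on both arrays. The centromeric histone Cenpa differed by 1.04, Hist3h2ba by 0.86, H2az1 by 0.71 and Macroh2a1 by 0.36. With only the 4 members above the 75th percentile of intensities, the histone list had percentile 97.3 and no longer stood apart.

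The HDAC list holds the family of the drug's targets and also the sirtuins, a separate family of deacetylases. It had a median of 0.20 (15 measured, percentile 97.2), short of standing apart, although quantile normalization brought the percentile to 98.0. Of the 15 genes, 11 were higher and 4 lower, and all 4 lower genes were HDACs. The sirtuins Sirt2, Sirt3, Sirt5, Sirt6 and Sirt7 differed by 0.20, 0.47, 0.13, 0.50 and 0.087. Hdac11 differed by -1.03, Hdac10 by -0.63, Hdac7 by -0.56 and Hdac6 by 0.63, whereas Hdac1, Hdac2 and Hdac3 differed by 0.27, -0.14 and 0.34. Genes often reported as higher after HDAC inhibition had a median of 0.074 (16 measured, percentile 87.3). In that list the testis-enriched heat shock gene Hspa2 differed by 0.91 and Sat1, an enzyme of polyamine breakdown, by 0.83, while the metallothioneins Mt1 and Mt2A differed by -0.59 and -0.83. Cdkn1a, which encodes the cell cycle inhibitor p21 and was chosen after its value was seen, differed by -0.27. Genes often reported as lower after HDAC inhibition had a median of 0.037 (13 measured, percentile 76.4), with Birc5 at 1.32, Ccnd1 at -0.86, Cdc25a at 0.72 and Myc at -0.49. Other chromatin regulators had a median of 0.00 (30 measured, percentile 64.3), with the corepressor Rcor1 at 0.84, Kat2a at -0.68, the remodeller Chd4 at 0.63 and Ncoa3 at 0.57.

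Circadian clock genes differed in both directions. All 17 measured genes were above the floor, 7 higher and 10 lower, and the list median was -0.37 (percentile 0.16). The activator Bmal1 differed by 2.53. The clock output gene Dbp differed by -1.96, the repressor Per2 by -1.85 and the repressor Bhlhe41 by -1.52. The labels give no hour of collection for either sample.

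**Figure D3:**
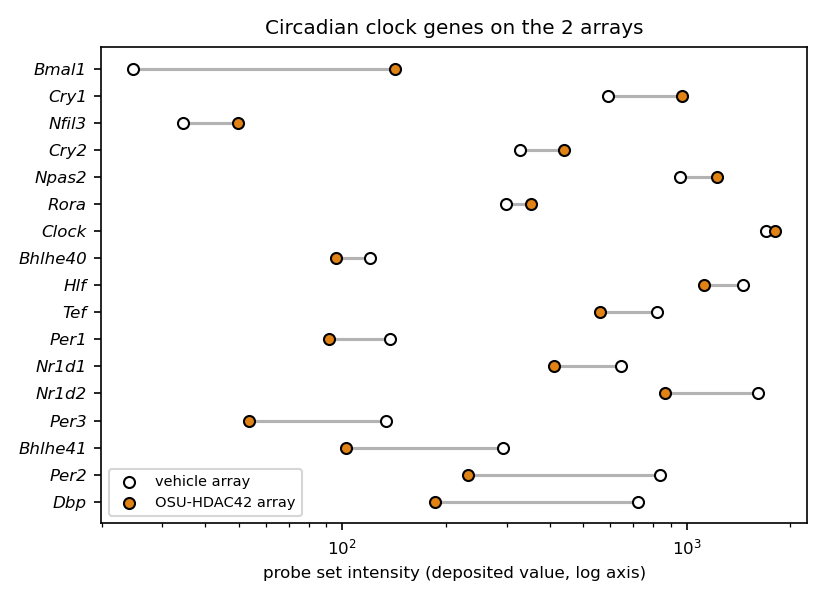
Probe set intensity (horizontal log axis) of the 17 circadian clock genes on the vehicle array (open points) and the OSU-HDAC42 array (filled points), sorted by their difference. Bmal1 stood at 143 against 24.7 and Dbp at 186 against 725.

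Genes of oxidative phosphorylation were slightly lower. In this list 35 of 44 genes were lower, none by 2-fold, with a median of -0.19 (1.14-fold lower) below all random lists. In the same sample the skeletal muscle list, from a tissue rich in mitochondria, had a median of -1.16, and a link between the lists was not tested. The complex I subunits Ndufs3 and Ndufs7 differed by -0.75 and -0.73, the ATP synthase subunit Atp5po by -0.70 and Cyc1 by -0.57. Glycolysis did not stand apart (20 measured, median -0.13, percentile 3.31), and its lowest members, Eno3 at -1.56 and Pgam2 at -1.32, are muscle isoforms that also stand on the skeletal muscle list. Without them the glycolysis median was -0.082 (percentile 10.7). Its members Gpi and Pfkfb3 differed by -0.56 and -0.47. Fatty acid oxidation (24 measured, median -0.077, percentile 18.7) did not stand apart, with the muscle form of carnitine palmitoyltransferase, Cpt1b, at -1.03, Acot2 at -0.56 and Plin2 at 0.38. Fatty acid synthesis (17 measured, median 0.00, percentile 53.2) held the desaturases Scd at 1.26 and Fads1 at 0.97, Dgat1 at 0.62 and the carboxylase Acaca at -0.58. Cholesterol synthesis (18 measured, median -0.074, percentile 18.6) held Stard4 at 0.99, Insig1 at 0.46, Mvd at -0.47 and Hsd17b7 at -0.45.

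Genes of the unfolded protein response were lower. Of the 20 measured genes of this list, 18 were lower (median -0.31, percentile 0.06), with Herpud1 at -0.83, Trib3 at -0.63, Dnajc3 at -0.53 and Creld2 at -0.52. Limited to the 13 members above the 75th percentile of intensities, this list reached percentile 2.71 and no longer stood apart. Genes of NRF2 and glutathione metabolism had a median of -0.11 (21 measured, percentile 2.20), with the glutathione transferases Gsta3 at -1.34, Gsta1 at -0.75 and Gstp1 at 0.80 and the heme oxygenase Hmox1 at -0.56. The mean of the same list was -0.12 and did not stand apart (percentile 6.22). Heat shock genes did not stand apart (13 measured, median -0.11, percentile 5.99). Among these, Hspb8 and Hsf1 differed by -0.43 each, Hspa1a by -0.32 and Hspa4l by 0.21.

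In signalling, p53 targets had a median of 0.22 (18 measured, percentile 99.5), with Gadd45a at 0.78, Xpc at 0.52, Plk2 at 0.46 and Aen at -0.43. Of their 14 members above the floor, 7 were higher and 7 lower, and those 14 had a median of -0.028. The Wnt, Notch and Hedgehog list, which also holds BMP and Id genes, was higher (32 measured, median 0.11, percentile 99.6). Of its 19 members above the floor, 14 were higher and 4 lower. Its largest differences were the BMP ligand Bmp2 at 1.31, the transcription factor Tcf7 at 1.05, the Wnt feedback gene Nkd1 at 0.82 and Dkk3 at 0.74. The median of this list was 0 when all intensities under 32 were raised to 32. Over its 11 members above the 75th percentile of intensities it was 0.085 (percentile 81.3). Apoptosis regulators did not stand apart (24 measured, median 0.079, percentile 89.5), although Apaf1, the scaffold of the apoptosome, differed by 1.05 and the BH3 protein Bcl2l11 by 0.80. In all, 12 of 47 lists stood apart, 6 higher and 6 lower, where independent random lists give 2.35 on average. As controls of RNA quality, the 3' over 5' intensity ratio was 6.29 for beta-actin and 2.09 for GAPDH in the OSU-HDAC42 sample, against 7.76 and 2.32 in the vehicle sample. For hexokinase, whose 5' probe set was below the floor on both arrays, the ratio went the other way, at 7.18 against 5.66.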

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

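The middle control probe set of beta-actin, an array control kept out of the gene results, was higher in the OSU-HDAC42 sample by 1.00 on the log2 scale, at 1305 against 651. The 3' and 5' probe sets of the same transcript differed by 0.51 and 0.81, and those of GAPDH by -0.30 and -0.15. Among probe sets of hybridisation controls, which are added in fixed amounts, 17 of 18 were lower in the OSU-HDAC42 sample, with a median of -0.12. These probe sets measure only the transcripts bioB, bioC, bioD and cre, so they are not 18 separate observations.

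Of the 9780 probe sets without a gene name, which no comparison of genes used, 3485 reached the expression floor. Of these, 97 were at least 2-fold higher and 105 at least 2-fold lower in the OSU-HDAC42 sample.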

How the results depend on the processing

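The skeletal muscle, cell cycle, smooth muscle, fibroblast and extracellular matrix, circadian clock and oxidative phosphorylation lists stood apart on the same side under every alternative run, with skeletal muscle medians from -1.28 to -1.02 and cell cycle medians from 0.63 to 0.81. Across all lists and alternatives, 508 list values stayed on their side of the threshold, 26 passed it newly, 11 no longer passed it and 3 reversed. For named genes 1476 values moved by less than the spread between probe sets and 75 by more. The median of all genes was 0.021 with each array centred, 0 with quantile normalization and -0.023 with the lowess trend removed, against 0 without them, and at the 2-fold threshold and main floor the share of higher genes among those counted ran from 35.2% to 40.2% over the scaling, probe set and raised-value alternatives. Raising no values, raising values under 32 to 32, and omitting shared muscle members were chosen after seeing the data. Low intensities leave 2320 of 14217 genes under 16 on both arrays, where no difference could be measured. No paired analysis was possible because each group had 1 array. Where no construction is named, the cause was not tested.

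With the floor at the 75th percentile 75 genes were higher and 119 lower, and the threshold gave 725 and 1042 at 1.5-fold and 31 and 57 at 3-fold, by construction. Limited to members above the floor, the p53 targets reversed to -0.028. The neuromuscular junction (-0.56), T and NK lymphocyte (0.85, 3 members left), mast cell (0.90, 3 members left) and cytosolic ribosomal protein (-0.060) lists then stood apart. Limited to the 75th percentile, p53 targets reversed to -0.19 and the endothelial list to 0.041 with 4 members left. There the unfolded protein response (-0.18), NRF2 and glutathione (-0.10), histone (0.46) and Wnt, Notch and Hedgehog (0.085) lists no longer stood apart, and cytosolic ribosomal proteins (-0.055) did.

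HDAC genes stood apart with quantile normalization (0.23), the lowess trend removed (0.22), the mean or median over probe sets (0.20 each) and unmatched random lists (0.20). The macrophage and myeloid list did so with quantile normalization (0.14), lowess (0.12), shared probe sets omitted (0.10) and the mean of members (0.19). With the mean over probe sets, apoptosis regulators (0.16) stood apart, and p53 targets (0.15) and NRF2 and glutathione (-0.11) did not. With the median over probe sets cytosolic ribosomal proteins (-0.063) did. By the mean of members, the granulocyte (-0.28), mast cell (0.40), glycolysis (-0.25) and apoptosis (0.24) lists stood apart, and NRF2 and glutathione (-0.12) did not. Against unmatched lists, NRF2 and glutathione (-0.11) did not, and the proteasome (0.081) did.

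With no values raised, the macrophage and myeloid (0.18), mast cell (0.51), red blood cell (-0.36) and apoptosis (0.25) lists stood apart and NRF2 and glutathione (-0.11) did not. With values under 32 raised to 32, p53 targets (0.021) and Wnt, Notch and Hedgehog (0) did not, and glycolysis (-0.13) did.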

Other observations

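Among immune cell genes, the macrophage and myeloid list had a median of 0.10 and did not stand apart (23 measured, 16 above the floor, percentile 96.7), with the mannose receptor Mrc1 at 1.00, the scavenger receptor Cd163 at 0.76 and the complement gene C1qa at 0.48. Class II histocompatibility genes had a median of -0.17 (9 measured, 8 above the floor, percentile 19.5), with RT1-Bb at -2.09, Cd74 at -0.66, RT1-DMa at 0.85 and RT1-Ba, the partner chain of RT1-Bb, at 0.82. In the mast cell list only 3 of 13 measured genes were above the floor, and all 3 were higher, namely Cpa3 at 1.46, the chymase Cma1 at 0.90 and Srgn at 0.63. Its median was 0.00 with low values raised and 0.51 (percentile 100) with none raised. The granulocyte, T and NK lymphocyte, B lymphocyte and plasma cell, interferon response, and NF-kB and inflammatory cytokine lists each had a median of 0.00, with percentiles of 50.0, 50.0, 49.9, 50.7 and 49.5. In the same order, 5 of 9, 11 of 19, 6 of 10, 9 of 29 and 5 of 27 measured members were under 16 on both arrays. For the granulocyte and lymphocyte lists this fixed the median at 0, so their percentiles say nothing on a difference. Random lists matched to the mast cell, interferon response, and nerve and glia lists also had medians of 0 over their central 95%. Single members were S100a8 at -1.43, Il7r at -1.27, Cd8a at 0.85, Blnk at -0.59, Isg15 at 0.79, Irf9 at -0.54, the cytokine Il18 at 1.15 and Ccl20 at -0.93.

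Genes of neighbouring organs were low in both samples. None of the 16 airway and cartilage genes and none of the 12 stomach genes measured was above the floor, and only 1 of 11 thyroid and parathyroid genes (Foxe1, at 0.37) and 1 of 15 liver and plasma protein genes (Serpina1, at -0.44) was. Under 16 on both arrays were 10, 11, 7 and 8 genes of these lists, which fixed each median at 0.00 and percentile at 50.0, so no difference could be assessed. Adipocyte genes had a median of 0.00 (17 measured, percentile 49.9), with Scd at 1.26 and Car3 at -0.89. Nerve and glia genes had a median of 0.00 (18 measured, 8 of them under 16 on both arrays, percentile 49.8) and red blood cell genes one of -0.022 (8 measured, percentile 9.42), with Hbb at -1.39 and Bpgm at 0.67.

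Several other groups stayed within the range of random lists. These were immediate early and stress genes (24 measured, median 0.00, percentile 55.1, with Nr4a3 at 1.72 and Myc at -0.49), xenobiotic metabolism (24 measured, 0.00, percentile 52.4, with Fmo2 at -0.79 and Fmo1 at 0.50) and glucocorticoid response genes (20 measured, -0.10, percentile 14.3, with Fam107a at -1.87 and Fkbp5 at 0.87). Cytosolic ribosomal proteins (34 measured, -0.055, percentile 3.69), the proteasome (28 measured, 0.081, percentile 89.9) and EGFR ligands and growth factor genes (29 measured, 0.00, percentile 55.2, with Igfbp3 at -0.91 and Tgfb2 at 0.61) did not stand apart either.

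The following genes, on no list, were chosen after their values were seen. In the direction of the skeletal muscle list were Jsrp1 at -1.93, Hjv at -1.90, Lmod2 at -1.78, Klhl31 at -1.73, the muscle-specific ribosomal protein Rpl3l at -1.58 and the muscle isoform Cox8b at -1.64. In the direction of the cell cycle list were the histone chaperone Asf1b at 1.62, the centromere gene Cenpp at 1.69, Psrc1 at 1.59 and the centriole gene Stil at 1.56, while the cyclin Ccnd2 stood at -1.90. Lgr5, a receptor of R-spondins, stood at 1.73, the serotonin transporter Slc6a4 at -1.64 and Adm at 1.66.

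All tests in the rest of this part were chosen after the values were seen. The lower skeletal muscle genes were weighed against an array-wide intensity trend. Median differences of all probe sets lay between -0.034 and 0.031 in every range of intensity examined. Removing a lowess trend could therefore hardly move the list median, which was -1.18 afterwards, and the removal adds no separate evidence. A trend of that size is too small to be the whole cause. With a smaller share of muscle in the tissue taken, genes made almost only by muscle should be lower by nearly the same amount, with an SD up to 1.5 times that of probe noise and not over 2 times. The SD of 36 such genes, 34 of them lower, was 2.14 times that of probe noise. The 36 include the slow-fibre troponins Tnnt1 (0.62) and Tnni1 (0.078), which lay near the floor and were not lower. How far the ratio rests on them was not tested. The limits also assume that an equal loss of muscle gives an equal difference at every intensity, which was not tested either. Over all probe sets, differences had an SD of 0.31 at mean log2 intensities from 10 to 12, against 0.53 from 6 to 8. The ratio therefore does not by itself count against a smaller share. A bootstrap interval added after the ratio was seen ran from 1.498 to 2.67 and so holds both limits. A smaller share of muscle and lower expression within the muscle therefore cannot be told apart here, and an effect of OSU-HDAC42 stays open and untested.

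The higher smooth muscle and cell cycle genes could follow from dilution, if less muscle RNA raised every cell type outside the muscle coat alike. The smooth muscle median exceeded the basal keratinocyte median by 0.68 (0.26 to 0.83), and the cell cycle median exceeded it by 0.70 (0.45 to 0.97). Over members above the 75th percentile of intensities these differences were 0.70 and 0.89. The contrasts were not matched on intensity, and several keratinocyte genes, such as Krt5, Krt14 and Krt15, are among the brightest. Differences had an SD of 0.16 at mean log2 intensities over 12, against 0.53 from 6 to 8. The keratinocyte contrasts therefore do not decide whether dilution was the whole cause. Smooth muscle exceeded the endothelial median by 1.11 (0.46 to 1.39). Over members above the 75th percentile, of which the endothelial list has 4, it did so by only 0.58 (0.00011 to 1.36). Vessels of the muscle coat could be lost with the muscle, and the layers taken are not given. The endothelial contrast therefore does not weigh against dilution. A general rise of proliferation genes would raise both lists alike, but the cell cycle median exceeded the DNA replication median by 0.63 (0.18 to 1.08). Both medians had been seen before this contrast was chosen, so it restates them. The replication genes as a list were not higher by as much as the cell cycle genes. Of those above the floor, 9 were higher and 9 lower, so a smaller rise of part of them is not excluded. These intervals cover the choice of genes and not the spread between rats, so a difference between individual samples and an effect of treatment both stay open.

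The clock genes could reflect samples taken at different phases of the daily cycle. Of 5 genes that peak with Bmal1 (Bmal1, Npas2, Clock, Cry1 and Nfil3), all 5 were higher (median 0.53), and of 10 targets of E-box and D-box elements, all 10 were lower (median -0.78), a difference of 1.31, while Cry2 and Rora, in neither group, differed by 0.42 and 0.24. Both groups were drawn up after the genes had been seen to go in opposite directions, so this difference restates the pattern and does not test a phase difference. The hour of collection was given for 0 of the samples in the labels. A difference in phase, different hours of collection and a clock shifted by treatment therefore cannot be told apart.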
